A study of Mus musculus with 14 samples.

How the data were processed

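Gene expression was measured in left ventricles of male mice of 2 closely related substrains, C57Bl/6J and C57Bl/6N, on 14 Illumina arrays. Each substrain contributed 3 arrays from sham-operated controls and 4 from mice given angiotensin II for 48 h. Angiotensin II is the effector peptide of the renin-angiotensin system; it constricts vessels and loads the heart. It was delivered from an osmotic mini-pump under the skin. The series title gives the dose as 500 ng/kg per minute and the design text as 500 ng/kg per hour, and nothing in the sources used here settles which is right. Per the labels' protocols, total RNA was extracted with a column kit and a DNase I step, checked on a Bioanalyser, and turned into biotin-labelled cRNA with the Ambion MessageAmp kit. The labels name each sample by its own number but do not state that each came from a separate mouse, so p-values measure the spread between these samples. Replicate numbers follow the order of the sample list and pair nothing, and no batch, chip or date was given.

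The authors deposited a table of signal intensity, on a linear scale, with a detection p-value for each of 18138 gene rows on each array. These intensities were neither background-subtracted nor normalised between arrays, judging from their values: the array medians ran from 80.8 to 112. They also deposited a value table of 18132 of these rows. Every column of it had a median intensity of 91.6, and its values differed from a quantile normalisation of the deposited intensities by a median of 4.97e-09 percent. It is therefore linear, not centred and not a ratio, and no question of scale, centring or direction stays open. The array model, the scanner software and the authors' reasons for leaving out the other 6 rows are not given in the sources used here. The files name rows by gene symbol with no probe sequences or coordinates, so no check of GC content was possible. Of the rows, 14309 matched a current symbol in a RefSeq gene table of the GRCm38.p6 assembly, 2662 matched through an older name, and 1167 matched nothing and keep the name in the file. The table was used for names only.

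The detection p-values of 14215 rows (78.4%) lay on a grid of 798 steps, within 0.2% of a step, the spacing that the rank of 1 probe among 798 negative controls would give; that reading comes from the values, not from a file header. The other 3923 rows lay off the grid and were taken to combine several probes. For these rows the detection p-value did not follow the signal. A row was therefore called above background on an array where its signal reached the lowest signal of a detected 1-probe row there. By that measure, 329 rows of several probes were above background on at least 3 arrays yet failed the filter below, and 323 passed it without being so.

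Intensities were normalised by the steps of neqc, built here from functions of limma 3.58.1 in R 4.3.3: background correction by a normal-exponential model, an added offset of 16, quantile normalisation and log2. The neqc function itself was run only as an alternative, with background inferred from all rows. The tables used here hold no control probes, so the background mean and SD of each array were inferred from the detection p-values. For each step of the grid the median signal of its rows stood for a negative control, with steps that held no row filled by linear interpolation, and the mean and SD of these values were taken. Only the 14215 rows on the grid were used for that, which gave background means of 60.8 to 74.2 and SDs of 11.6 to 18.5. Use of all rows gave SDs of 169 to 290. That restriction, and the signal-based measure of background, were chosen after the files had been seen; both versions are among the alternatives. The tested rows were the 9408 (51.9%) with a detection p-value under 0.05 on at least 3 arrays, the size of the smallest group. Between 46.4% and 49.3% of rows were detected on each array. The number of arrays limits the precision of every comparison.

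One linear model with a mean for each of the 4 groups was fitted to all 14 arrays with lmFit, contrasts.fit and eBayes, with 10 residual and 4.8 prior degrees of freedom. The contrasts were angiotensin II against sham in each substrain, the difference between these responses, the substrains against each other in sham and under angiotensin II, and the treatment and substrain effects averaged. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 9408 rows are called higher or lower, and every adjusted p for a gene comes from this limma fit. A fold change is on the scale of log2 signal after the offset, which understates the change of dim genes. Where no array of a group was above background, the change is given as at least N-fold, and a difference of responses or an average over groups is given no size. That bound sets the mean of the brighter group against the mean, over the dim arrays, of the higher of the lowest detected signal and the gene's own.

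Fixed before the data were examined were 33 gene lists: 20 of pathways, 12 of cell type markers and 1 of genes known to differ between the substrains. They held 700 entries, of which 643 had a row and 490 were tested. Each list was tested in each contrast with camera, two-sided, at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists. The same test with a correlation estimated from the data, and fry, were alternatives. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Counts of list members past the threshold are given over all genes tested and, as stated, adjusted over the list alone. 

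Named genes followed a rule fixed before the data were examined. In each treatment contrast these are the 10 largest rises and 10 largest falls among genes past the threshold whose 4 treated arrays all lie beyond all 3 sham arrays, and up to 4 passing members of each list described, by size of change. In the substrain contrasts these are the 5 largest rises and falls that passed, and where fewer than 5 genes passed in all, the 5 of smallest p. Nppa, Nppb, Myh7, Acta1, Col1a1, Col3a1, Postn, Timp1, Ccn2 (listed under its older name Ctgf), Ccl2, Agtr1a and Nnt were to be reported whatever their values. Predicted genes without a symbol were passed over, and only some of the list members that qualify are printed. Some genes that the rule names are not reported here.

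The scripts were tested on simulated data with independent noise between genes and 200 genes changed by known amounts among the 9408. For the C57Bl/6J response, 44.8% of genes simulated with a log2 change of 0.5 were recovered, 94.0% at 1 and 98.5% at 2. For the C57Bl/6N response these shares were 56.7%, 95.5% and 100%, and for the difference between responses 8.96%, 68.7% and 100%. All simulated arrays shared 1 spread per gene, so the shares of the substrains differ only through the genes and noise drawn. Extra spread on a single real array was not simulated. Between 4 and 5 unchanged genes were called in each simulation. A simulated shift of 0.5 in the extracellular matrix list in C57Bl/6J was called by all of the list tests, with 0 of the 32 other lists called by camera. The simulated noise held no correlation between genes, so this does not carry over to lists whose genes move together. No pair of arrays held identical values, and correlations between arrays ran from 0.962 to 0.996. The Y-linked genes Ddx3y and Eif2s3y were above background on 14 arrays and Xist on 0, as the labels' male sex requires. Nnt, which carries a known deletion in C57Bl/6J, was above background on 0 arrays, so its row checks nothing about the substrain labels.

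The alternatives were other background corrections and scalings, the deposited value table, other filters on dim rows, robust variance moderation with an intensity trend, array weights, fits of only the groups compared, other thresholds, and leaving out each array in turn. Chosen after the data had been seen were the background inferred from all rows, the filter on signal, and leaving out C57Bl/6J angiotensin II 1 and C57Bl/6N sham 1 together.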

Results

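Transcript levels were measured in left ventricles of male C57Bl/6J and C57Bl/6N mice after 48 h of angiotensin II or a sham operation. Each substrain had 3 sham arrays and 4 angiotensin II arrays, 14 in all. Of 18138 gene rows, between 46.4% and 49.3% were detected on each array, and 9408 genes were tested. Array medians of the deposited signal ran from 80.8 to 112 before normalisation. Correlations of normalised values between arrays of the same group were 0.976 or higher.

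In C57Bl/6J ventricles, angiotensin II raised genes of the cardiac stress response and some genes of the extracellular matrix and of its proteases and inhibitors. Of these 3 lists, cardiac stress alone kept its camera call with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, rose 6.48-fold (log2 change 2.70 ± 0.43 SE, adjusted p = 0.00855). Ccn2, a matricellular protein induced by TGF-beta, rose 3.54-fold (1.82 ± 0.15, adjusted p = 2.92e-05). Myh7, the fetal myosin heavy chain of the mouse ventricle, rose 2.13-fold (adjusted p = 0.0139), and Nppa, which encodes atrial natriuretic peptide, rose 2.25-fold (adjusted p = 0.0314). In all, 94 genes were higher and 35 lower among the 9408, and 25 of the higher genes and 0 of the lower ones changed by at least 2-fold. At an unadjusted p under 0.05 in limma there were 1437.

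The other large rises were in Socs3, a feedback inhibitor of cytokine signalling (log2 change 1.85), Thbs1 (1.83), Rcan1, a target of calcineurin signalling (1.79, adjusted p = 0.0492), and Lox, which cross-links collagen (1.68). Actg2 rose by 1.29. Egr2, an immediate early transcription factor above background on 2 of 3 sham arrays, rose by 1.26. Tnc, which encodes tenascin C, was above background on 0 of 3 sham arrays and 4 of 4 treated arrays, and was at least 1.93-fold higher. Ptx3 was above background on 0 of 3 sham and 3 of 4 treated arrays, and was at least 1.59-fold higher. The largest falls were smaller. They were in Inmt (-0.99), Acot1, a cytosolic acyl-CoA thioesterase (-0.84), Aplnr, the apelin receptor (-0.84), Srrm4 (-0.78), Frat2 (-0.76), Slc46a1 (-0.75) and Abhd1 (-0.75). Slc46a1 was above background on 3 and Abhd1 on 1 of the 4 treated arrays. Poln was at least 1.49-fold lower, Sh3yl1 at least 1.26-fold lower and Chrna2 at least 1.18-fold lower, each above background on 0 of 4 treated arrays.

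Of the genes to be reported whatever their values, Acta1, skeletal alpha-actin, rose 2.38-fold in C57Bl/6J (adjusted p = 0.00927). Nppb had a log2 change of 1.29 ± 0.31 and missed the threshold (adjusted p = 0.0572), as did the collagen gene Col3a1 (0.87 ± 0.23, adjusted p = 0.0829) and the chemokine gene Ccl2 (1.49 ± 0.48, adjusted p = 0.153), which was above background on 1 of 3 sham arrays. Col1a1 had a log2 change of 0.00 ± 0.50 (adjusted p = 0.999) and Agtr1a, the main angiotensin receptor gene, -0.22 ± 0.15 (adjusted p = 0.495). Postn was above background on 0 of the 14 arrays.

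Among the fixed lists in C57Bl/6J, cardiac stress and hypertrophy genes rose: 10 of 19 tested members passed, and 17 when adjusted over the list alone (camera adjusted p = 9.47e-20, and 0.0101 with an estimated correlation). Tnfrsf12a (1.26) and Uck2 (1.18) were among them. Of 29 genes of fibrillar collagen and extracellular matrix, 8 rose, and 16 adjusted over the list alone (camera adjusted p = 3.08e-14; adjusted p = 0.0844 with an estimated correlation). Of 25 genes of actin cytoskeleton remodelling, 2 rose, Tubb6 (1.17) and Actb (0.52), and 7 adjusted over the list alone (camera adjusted p = 9.13e-10; adjusted p = 0.334 with an estimated correlation). Adamts1 (1.07) and Adamts2 (0.52) rose among 17 matrix proteases and inhibitors, with 5 higher adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.114 with an estimated correlation). Socs3 and Ptx3 were the 2 that rose among 24 chemokines and inflammatory mediators, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.459 with an estimated correlation).

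Egr2 and Ier3 (0.72) rose among 14 immediate early genes in C57Bl/6J, with 6 higher adjusted over the list alone (camera adjusted p = 0.000274; adjusted p = 0.334 with an estimated correlation). Their median was -0.41, -0.08 and 0.39 on sham 1, 2 and 3, apart from one another, and 0.12, 0.37, 0.30 and 0.38 on the treated arrays, all below sham 3. Cdkn1a (1.25) and Fkbp5 (0.87) rose among 10 genes of the glucocorticoid response, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000344; adjusted p = 0.145 with an estimated correlation). Acot1 fell among 28 genes of fatty acid oxidation, with 2 lower adjusted over the list alone (camera adjusted p = 0.00622; adjusted p = 0.577 with an estimated correlation). No member passed by limma over all genes tested in the remaining 4 lists that camera called. These were cell cycle, up, with 1 of 21 higher adjusted over the list alone (adjusted p = 0.000281), endoplasmic reticulum stress, up, with 4 of 16 (adjusted p = 0.00418), interferon response, down, with 1 of 20 lower (adjusted p = 0.0129), and macrophage and monocyte markers, up, with 0 of 22 (adjusted p = 0.0333). With an estimated correlation their adjusted p was 0.577, 0.404, 0.577 and 0.784.

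Beside these C57Bl/6J groups, the median of macrophage and monocyte markers, relative to the mean of the 6 sham arrays, was 0.16 to 0.24 on the treated arrays and -0.03 to 0.20 on the sham arrays. The median of atrial markers was 1.0, 0.51, 0.72 and 0.73 on the treated arrays and 0.48, -0.02 and -0.06 on the sham arrays (camera adjusted p = 0.073). On C57Bl/6J angiotensin II 1, which lay over 1 log2 unit from the other 3 of its group in 302 genes, the cardiac stress median was 0.80 against 0.64 to 0.71 on the other 3 arrays, and the extracellular matrix median was 0.44 against 0.52 to 0.72. The count of 129 genes became 1 without C57Bl/6J sham 2, 32 without sham 1, 45 without sham 3, 85 without angiotensin II 3 and 60 without angiotensin II 4. With median scaling 92 genes passed and 47.8% of them were higher, in place of 72.9%. Of the 38 named calls, 37 were lost without at least 1 array, Ccn2 alone being kept in each. The call of the interferon list ended without sham 1 (adjusted p = 0.217) or angiotensin II 2 (0.0918), and that of the macrophage list without sham 2 (0.109), sham 3 (0.129), angiotensin II 2 (0.0738) or angiotensin II 3 (0.0573), and in 4 of the 5 other scalings. Among the 5, the deposited value table and quantile normalisation without background correction are in effect 1 scaling.

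**Figure D1:**
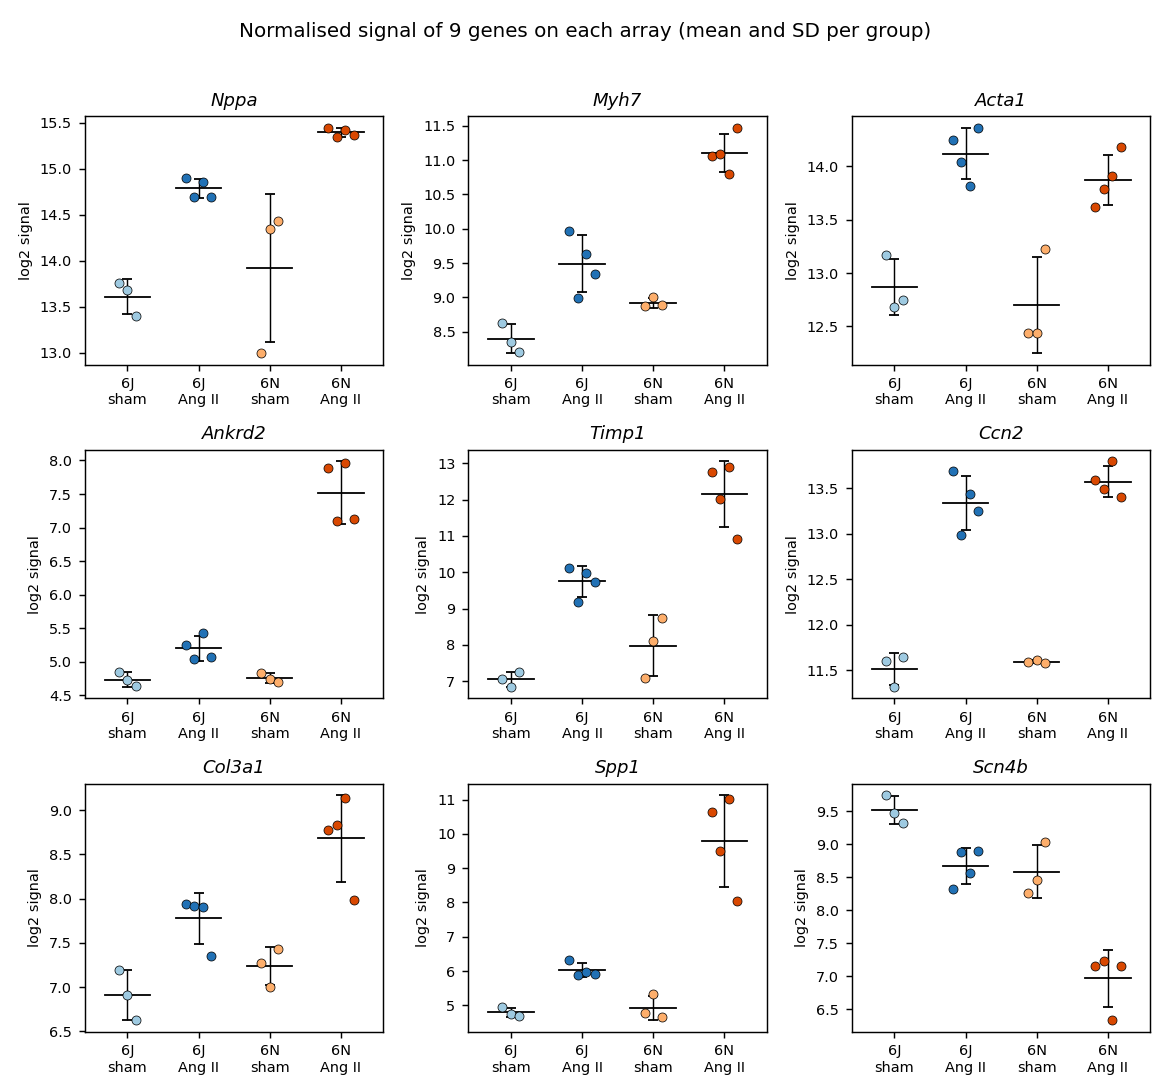
Normalised log2 signal of 9 genes (y axis) on each of the 14 arrays, by group (x axis); points are arrays and bars the group mean ± SD (n = 3 sham and 4 angiotensin II arrays per substrain). Timp1 and Ccn2 were higher under angiotensin II in both substrains, and Spp1 was above background on 0 of 6 sham arrays.

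In C57Bl/6N ventricles, angiotensin II raised matrix, cytoskeletal, cell cycle and macrophage genes and lowered genes of fatty acid oxidation and of ion channels. Of these groups, the matrix list alone kept its camera call with an estimated correlation. Spp1, which encodes osteopontin, was above background on 0 of 3 sham arrays and 4 of 4 treated arrays and was at least 19.1-fold higher (adjusted p = 6.63e-05). Timp1 rose 18.0-fold (log2 change 4.17 ± 0.43 SE, adjusted p = 7.68e-05), and Tnc was at least 10.7-fold higher (adjusted p = 4.1e-05). Scn4b, a sodium channel beta subunit, fell by 1.61 ± 0.23 on the log2 scale (adjusted p = 0.000475). In all, 889 genes were higher and 745 lower among the 9408, and 181 of the higher and 21 of the lower changed by at least 2-fold. At an unadjusted p under 0.05 in limma there were 2952.

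The other large rises in C57Bl/6N included Lox (2.78), Prc1 (2.78) and Top2a (2.62), which act in cell division, and the histone genes H2ac7 (2.79) and H2ac12 (2.68). Top2a was above background on 1 and H2ac12 on 2 of the 3 sham arrays. Arg1, an arginase of activated macrophages, was at least 4.16-fold higher and Ankrd2, a stretch-responsive ankyrin repeat protein of muscle, at least 3.92-fold higher, each above background on 0 of 3 sham and 4 of 4 treated arrays. The other large falls were in Erdr1 (-2.15, above background on 3 of 3 sham and 1 of 4 treated arrays), Kcnv2, a potassium channel subunit (-1.78), Ano10 (-1.45), Ift81 (-1.23), Wnk2 (-1.21), Lgals4 (-1.18), Kcnip2, a subunit of the transient outward current (-1.15), and CES3, named as in the file (-1.15). Pkd2l2 was at least 1.68-fold lower. Of the genes fixed in advance, Myh7 rose 4.55-fold (adjusted p = 4.1e-05), Ccn2 3.93-fold (4.84e-06), Nppa 2.77-fold (0.0015), Col3a1 2.72-fold (0.00112) and Acta1 2.25-fold (0.00171). Nppb rose 2.40-fold (adjusted p = 0.0127) and Col1a1 3.66-fold (adjusted p = 0.0185). Ccl2, above background on 2 of 3 sham arrays, had a log2 change of 1.03 ± 0.48 (adjusted p = 0.156) and Agtr1a of -0.28 ± 0.15 (adjusted p = 0.205).

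Of 29 extracellular matrix genes, 23 rose in C57Bl/6N, and 25 adjusted over the list alone (camera adjusted p = 7.41e-21, and 0.0231 with an estimated correlation). Of 19 cardiac stress genes, 14 rose, Uck2 by 1.97 and Rcan1 by 1.67, and 18 adjusted over the list alone (camera adjusted p = 6.23e-16, and 0.0231 with an estimated correlation). Of 25 actin cytoskeleton genes, 21 rose, with Tubb2b at 1.55, S100a11 at 1.37 and Vim at 1.22, and 25 adjusted over the list alone (camera adjusted p = 8.11e-18; adjusted p = 0.161 with an estimated correlation). Of 21 cell cycle genes, 19 rose, Birc5 to at least 3.81-fold, and 20 adjusted over the list alone (camera adjusted p = 1.19e-16; adjusted p = 0.173 with an estimated correlation). Of 22 macrophage and monocyte markers, 19 rose, with Lgals3 at 2.50 and Cd52 at 1.84, and 21 adjusted over the list alone (camera adjusted p = 5.46e-16; adjusted p = 0.173 with an estimated correlation).

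Of 16 cytosolic ribosomal protein genes, 10 rose in C57Bl/6N, Rpl3 by 0.89 and Rps16 by 0.71, and 12 adjusted over the list alone (camera adjusted p = 1.43e-06; adjusted p = 0.173 with an estimated correlation). Their median was -0.38 on sham 1, apart from 0.13 and 0.03 on sham 2 and 3, and 0.54, 0.37, 0.58 and 0.18 on angiotensin II 1 to 4. Of 17 matrix proteases and inhibitors, 6 rose and 1 fell, with Serpinb1a at 1.58 and Adamts4 at 1.13, each above background on 1 of 3 sham arrays, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.00533, up; adjusted p = 0.0788 with an estimated correlation). Of 24 chemokines and inflammatory mediators, 5 rose and 2 fell, with Lcn2, lipocalin 2, at 2.22 and Ccl9 at 0.94, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.00486, up; adjusted p = 0.446 with an estimated correlation).

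Of 28 fatty acid oxidation genes, 18 fell in C57Bl/6N, with Ucp3 at -1.06, Acot1 at -0.99 and Decr1 at -0.88, and 22 adjusted over the list alone (camera adjusted p = 2.14e-10; adjusted p = 0.173 with an estimated correlation). Their median was 0.27 on sham 1, apart from -0.05 and -0.12 on sham 2 and 3, and -0.58, -0.49, -0.68 and -0.35 on angiotensin II 1 to 4. Of 18 genes of cardiac ion channels and calcium handling, 8 fell and 1 rose, with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at -0.74, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000671, down; adjusted p = 0.257 with an estimated correlation). Of 32 oxidative phosphorylation genes, 5 fell, among them Ndufa10 at -0.44, and 5 adjusted over the list alone (camera adjusted p = 0.00319; adjusted p = 0.31 with an estimated correlation).

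Camera did not call the list of oxidative stress defence in C57Bl/6N (adjusted p = 0.331), in which 6 of 18 members rose and 5 fell, the same numbers adjusted over the list alone. Hmox1, heme oxygenase 1, rose 5.0-fold, and Prdx3, a mitochondrial peroxiredoxin, fell by 0.49 on the log2 scale. Of 17 genes of glycolysis and glucose transport, 4 rose and 5 fell, and 5 and 6 adjusted over the list alone (camera adjusted p = 0.65). Of 15 genes of TGF-beta family signalling, 4 rose and 1 fell, the same numbers adjusted over the list alone, with Tgfbi at 1.53 and Inhba at 1.07 (camera adjusted p = 0.136).

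Beside the C57Bl/6N groups, the median of macrophage and monocyte markers was 1.12, 0.91 and 1.36 on angiotensin II 1 to 3 and 0.28 on angiotensin II 4, and that of cell cycle genes was 1.35, 1.09, 1.52 and 0.44 on the same arrays. Cardiomyocyte markers lay at -0.21, -0.03, -0.21 and -0.02 there and at 0.15, 0.03 and -0.02 on sham 1, 2 and 3 (camera adjusted p = 0.144). Endothelial markers lay at -0.27, -0.26, -0.26 and -0.03, and at 0.03, -0.02 and -0.05 on the shams (camera adjusted p = 0.0859). The cardiac stress medians on the treated arrays were 1.06, 1.0, 1.62 and 1.03, and the atrial marker medians -0.53, -0.42, -0.58 and -0.25, against -0.76, 0.49 and 0.03 on sham 1, 2 and 3. The count of 1634 genes became 968 without C57Bl/6N sham 1, 958 without angiotensin II 1 and 950 without angiotensin II 3. Each of the 11 list calls was kept without each array. Of the 103 named calls, 34 were lost without at least 1 array, among them Nppb without sham 1 (adjusted p = 0.0517), Kcnip2 without sham 1 (0.0507), Col1a1 without sham 1 (0.0779), sham 2 (0.0605) or angiotensin II 1 (0.0505), Rcan1 without sham 1 (0.0862) or sham 2 (0.0776), Ccl9 without sham 2 (0.0578), Ndufa10 without sham 1 (0.0623), Ucp3 without sham 1 (0.13), sham 2 (0.0692), angiotensin II 2 (0.0629) or angiotensin II 3 (0.089), and Decr1 without sham 1 (0.193), sham 2 (0.074), angiotensin II 1 (0.0936) or angiotensin II 3 (0.0891).

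**Figure D2:**
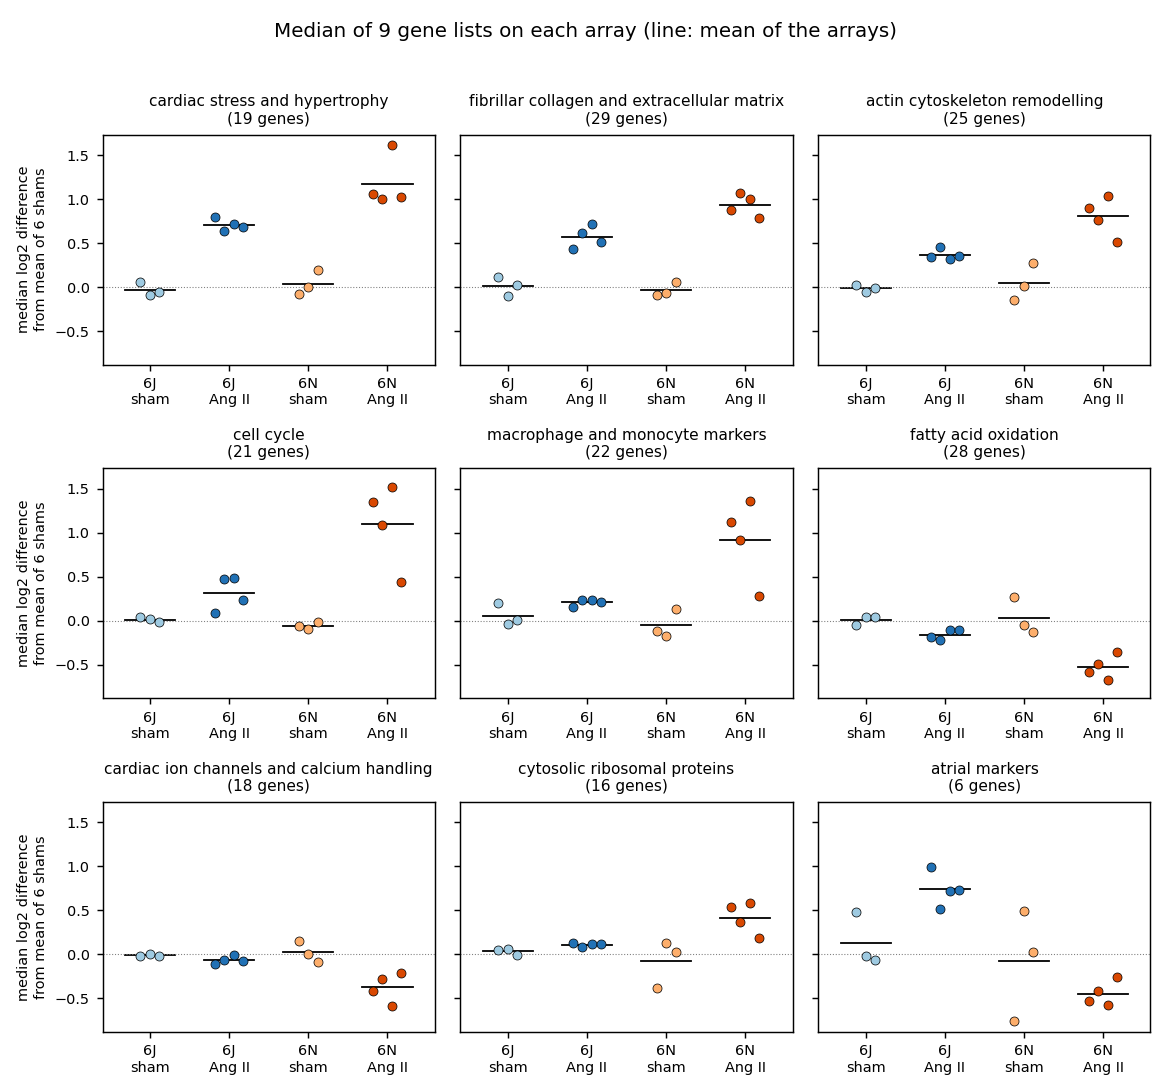
Median log2 difference from the mean of the 6 sham arrays (y axis) over the tested members of 9 gene lists, for each array by group (x axis); points are arrays and lines the mean of a group's arrays. Macrophage and monocyte markers lay at 0.91 to 1.36 on C57Bl/6N angiotensin II 1 to 3 and at 0.28 on angiotensin II 4.

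The responses of the substrains shared genes such as Timp1, Ccn2, Lox, Myh7 and Acta1. Of the 129 genes called in C57Bl/6J and the 1634 called in C57Bl/6N, 84 were called in both and 83 of these changed in the same direction. That was 70 genes higher in both, against 8.88 for independent lists, and 13 lower in both, against 2.77. The C57Bl/6J count fell to 1 without C57Bl/6J sham 2, which caps the overlap at 1 in that fit. The substrains have separate sham arrays, so no shared control adds to the overlap. Both lists come from 1 fit with a shared variance for each gene, so the numbers for independent lists may be too low. Of the C57Bl/6N calls, 1335 (81.7%) had the same sign in C57Bl/6J, and of the 129 C57Bl/6J calls 121 had the same sign in C57Bl/6N. Across the 9408 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.397 and Spearman rho = 0.266, and r ran from 0.331 to 0.515 as each array was left out.

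**Figure D3:**
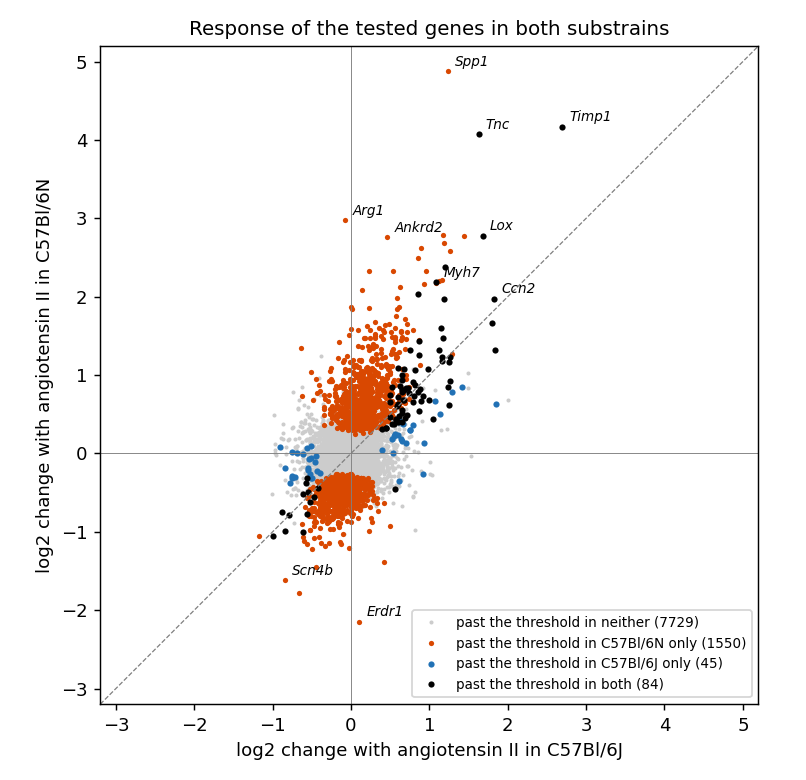
Log2 change under angiotensin II in C57Bl/6J (x axis) against that in C57Bl/6N (y axis) for the 9408 tested genes; each point is a gene, coloured by the substrain in which it was called, and the dashed line marks equal changes. Of the genes, 84 were called in both substrains, 45 in C57Bl/6J and not in C57Bl/6N, and 1550 in C57Bl/6N and not in C57Bl/6J.

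The test of whether the response differed between substrains called a single gene, Ankrd2, whose response was larger in C57Bl/6N (adjusted p = 0.00417). It was above background on 4 of 4 C57Bl/6N angiotensin II arrays and on 0 of the other 10, so the difference of the responses is given no size. The genes of next smallest p missed the threshold: Fcgr4, an Fc receptor (1.21), Sla (1.17) and Gfpt2 (-1.43), each at an adjusted p of 0.0613, and Sppl2a (-1.01, adjusted p = 0.0682). Myh7 (1.10 ± 0.28, adjusted p = 0.129), Timp1 (1.47 ± 0.60, 0.237), Col1a1 (1.87 ± 0.70, 0.215), Col3a1 (0.58, 0.358), Nppa (0.30, 0.676), Nppb (-0.03, 0.981), Acta1 (-0.08, 0.909), Ccn2 (0.15, 0.722), Ccl2 (-0.47, 0.739) and Agtr1a (-0.06, 0.904) did not pass either. At an unadjusted p under 0.05 there were 1644 genes.

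As groups, macrophage and monocyte markers responded more in C57Bl/6N, with 0 of 22 past the threshold over all genes in limma and 16 adjusted over the list alone (median difference 0.83, camera adjusted p = 6.84e-12). So did cell cycle genes, with 0 of 21 and 16 (0.90, adjusted p = 5.02e-11), extracellular matrix genes, with 0 of 29 and 6 (0.60, adjusted p = 2.21e-07), actin cytoskeleton genes, with 0 of 25 and 5 (0.44, adjusted p = 9.33e-07), and ribosomal protein genes, with 0 of 16 and 0 (0.39, adjusted p = 3.61e-05). The difference was negative for fatty acid oxidation (-0.36, adjusted p = 8.52e-06), cardiac ion channels (-0.45, adjusted p = 0.000958), oxidative phosphorylation (-0.12, adjusted p = 0.0301), endoplasmic reticulum stress (-0.29, adjusted p = 0.0402) and atrial markers (-0.63, adjusted p = 0.0253), with 0 members past the threshold in each either way, and for cardiomyocyte markers (-0.18, adjusted p = 0.0301), with 2 lower adjusted over the list alone. For cardiac stress genes the median (-0.03) and the mean (0.35) differed in sign and camera called the list up (adjusted p = 0.0459), with Ankrd2 past the threshold and 3 adjusted over the list alone; with median scaling the median was 0.02. None of these 12 calls held with an estimated correlation, where the adjusted p was 0.448 or 0.458. The cardiac stress call was also lost in each of the 5 other scalings (adjusted p 0.0605 to 0.157), and that of endoplasmic reticulum stress with background from all rows (0.0821). Among the 5, the deposited value table and quantile normalisation without background correction gave the same counts and are in effect 1 scaling.

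Without C57Bl/6N angiotensin II 4, whose macrophage median was 0.28, the count of genes that differed in response was 415 in place of 1. It was 2 without C57Bl/6J sham 3 or C57Bl/6J angiotensin II 2, and 0 without background correction, with the other offset, in the deposited value table, with background from all rows or without both C57Bl/6J angiotensin II 1 and C57Bl/6N sham 1. The list calls of cardiac stress (lost without each of C57Bl/6J sham 1, C57Bl/6J angiotensin II 2, 3 and 4, C57Bl/6N sham 1 and 2 and C57Bl/6N angiotensin II 3, adjusted p 0.0631 to 0.432), endoplasmic reticulum stress (8 arrays, 0.0631 to 0.197), oxidative phosphorylation (6 arrays, 0.0515 to 0.156), cardiomyocyte markers (5 arrays, 0.0511 to 0.169) and atrial markers (5 arrays, 0.0533 to 0.146) each ended when single arrays were left out.

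In sham ventricles, 2 genes differed between the substrains. Rab4a, a small GTPase of endosome recycling, was 3.35-fold higher in C57Bl/6N (log2 difference 1.74 ± 0.18 SE, adjusted p = 0.000564), and Entpd4, a nucleotidase of the Golgi, was 1.67-fold lower (-0.74 ± 0.11, adjusted p = 0.0306). Entpd4 is on the list of genes known to differ between the substrains, of which 5 were tested and the other 4 did not pass over all genes; adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.175). Gfpt2 (1.01), Cdkn1a (1.05) and Hsd17b7 (0.55) had an adjusted p of 0.129 each. At an unadjusted p under 0.05 in limma there were 717 genes. Genes of endoplasmic reticulum stress lay higher in C57Bl/6N sham ventricles, with 0 of 16 past the threshold over all genes and 6 adjusted over the list alone (median 0.40, camera adjusted p = 6.24e-09; adjusted p = 0.199 with an estimated correlation). Smooth muscle and pericyte markers lay lower, with 0 of 15 either way (median -0.14, camera adjusted p = 0.039; adjusted p = 0.397 with an estimated correlation). The Entpd4 call ended when any of 8 arrays was left out: C57Bl/6J sham 1, 2 and 3, C57Bl/6J angiotensin II 3, C57Bl/6N sham 2 and 3, and C57Bl/6N angiotensin II 2 and 3 (adjusted p 0.0662 to 0.215). The count was then 1, and it was 4 without C57Bl/6N sham 1. The smooth muscle call ended without C57Bl/6J sham 1 (adjusted p = 0.06), C57Bl/6J sham 3 (0.0588), C57Bl/6N angiotensin II 4 (0.051) or C57Bl/6N sham 3 (0.093).

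Under angiotensin II, 513 genes were higher and 356 lower in C57Bl/6N than in C57Bl/6J. Spp1 was 13.6-fold higher (log2 difference 3.77 ± 0.45 SE, adjusted p = 0.000587), Tnc 5.67-fold and Timp1 5.26-fold. Arg1 was at least 4.19-fold and Ankrd2 at least 3.95-fold higher, each above background on 0 of 4 C57Bl/6J arrays. Lower in C57Bl/6N were Erdr1 (-2.72, above background on 1 of 4 C57Bl/6N arrays), the heat shock gene Hspa1a (-2.01), Hamp, which encodes the iron hormone hepcidin (-1.87, above background on 3 of 4 C57Bl/6N arrays), the stress transcription factor Atf3 (-1.83) and Scn4b (-1.70). Of the genes known to differ between substrains, Wdfy1 was at least 1.57-fold higher (adjusted p = 9.27e-05) and Entpd4 lower (-0.94, adjusted p = 9.64e-05).

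Of 21 cell cycle genes, 17 were higher in C57Bl/6N under angiotensin II, and adjusted over the list alone 20 were higher and 1 lower (camera adjusted p = 1.28e-12). Of 22 macrophage and monocyte markers, 12 were higher, with Lgals3 at 1.98, and 19 adjusted over the list alone (adjusted p = 7.3e-12). The numbers were 12 of 29, and 14 higher and 2 lower over the list alone, for extracellular matrix (adjusted p = 5.18e-08), and 10 of 25, and 18, for actin cytoskeleton (adjusted p = 1.59e-10). They were 6 of 19, and 7 higher and 1 lower, for cardiac stress (adjusted p = 0.0121), 5 of 17, and 7 higher and 1 lower, for matrix proteases (adjusted p = 0.0127), and 2 of 16, and 7, for ribosomal proteins (adjusted p = 9.01e-05). Lower in C57Bl/6N were 7 of 28 fatty acid oxidation genes, and 20 adjusted over the list alone (adjusted p = 5.09e-09); 5 of 18 ion channel genes, and 6 (adjusted p = 0.000357), with Kcnd2 at -0.71; and 3 of 6 atrial markers, and 5 (adjusted p = 9.48e-05), with Mybphl at -1.54, Myl4 at -1.04 and Stard10 at -0.85. Oxidative phosphorylation genes lay lower with 0 of 32 past the threshold either way (adjusted p = 9.01e-05). With an estimated correlation none of these 11 calls held: the adjusted p was 0.39 for cardiac stress, 0.26 for ribosomal proteins, 0.256 for ion channels and 0.255 for the other 8.

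The atrial marker medians beside these groups were 0.51 to 1.0 on the C57Bl/6J angiotensin II arrays and -0.58 to -0.25 on the C57Bl/6N ones. The count of 869 genes became 198 without C57Bl/6N angiotensin II 1, 463 without angiotensin II 2, 211 without angiotensin II 3, 1473 without angiotensin II 4 and 426 without C57Bl/6J angiotensin II 4. Of 74 named calls, 42 were lost without at least 1 array, among them Hspa1a (5 arrays, adjusted p 0.0791 to 0.108), Atf3 (2 arrays, 0.0592 and 0.0819), Mybphl (2 arrays, 0.0604 and 0.0619) and Myl4 (4 arrays, 0.0576 to 0.0885). With median scaling, 78.1% of the called genes were higher in place of 59.0%, and the calls of the cardiac stress (adjusted p = 0.152) and matrix protease (0.063) lists ended.

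Averaged over both substrains, angiotensin II raised 783 genes and lowered 704, of which 72 and 5 changed by at least 2-fold. With median scaling 613 were higher and 722 lower, so which direction held more genes depended on the processing. Of 19 cardiac stress genes, 17 rose, and 19 adjusted over the list alone (camera adjusted p = 2.6e-21, and 0.00796 with an estimated correlation). Of 29 extracellular matrix genes, 21 rose, and 23 adjusted over the list alone (adjusted p = 5.49e-22, and 0.0192 with an estimated correlation). Of 17 matrix proteases and inhibitors, 8 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.00165, up, and 0.0396 with an estimated correlation). The count became 970 without C57Bl/6J sham 2.

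Averaged over both treatments, 94 genes were higher and 93 lower in C57Bl/6N. Rab4a (1.76 ± 0.12 SE, adjusted p = 1.83e-06) and Timp1 (1.66) were higher. Spp1 (adjusted p = 0.0104), Tnc (0.0248) and Arg1 (0.0297) passed as higher too, but were above background on 0 of the 6 sham arrays, so their averaged differences are given no size. Erdr1 (-1.59), Hamp (-1.45), Scn4b (-1.32) and Retnla, a marker of alternatively activated macrophages (-1.22), were among the largest negative ones. Of the substrain genes, Entpd4 was lower (-0.84 ± 0.07, adjusted p = 3.57e-05) and Wdfy1, above background on 0 of the 7 C57Bl/6J arrays, higher (adjusted p = 0.000632), whereas Ide (-0.33, 0.297), Cyfip2 (-0.42, 0.189) and Snap29 (-0.06, 0.848) did not pass. The count of 187 became 68, 73 and 84 without C57Bl/6J sham 1, 2 and 3, 107 and 110 without C57Bl/6J angiotensin II 2 and 4, 113, 101 and 123 without C57Bl/6N sham 1, 2 and 3, 82 and 91 without C57Bl/6N angiotensin II 1 and 3, 311 without C57Bl/6J angiotensin II 1 and 608 without C57Bl/6N angiotensin II 4. The calls of Arg1 and Tnc were lost when any of 11 and 9 of the 14 arrays was left out (adjusted p 0.0505 to 0.0825).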

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

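The regroupings of arrays and the shuffle of substrain labels were planned; the tests of single arrays, of the scaling, of labels and of cell types were chosen only after the results had been seen.

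Far more genes passed under angiotensin II in C57Bl/6N (1634) than in C57Bl/6J (129). The ratio of counts depended on the threshold. At an adjusted p of 0.10 in limma the counts were 2307 and 267, and at an unadjusted p under 0.05 they were 2952 and 1437. Reassigning the substrain within each treatment gave a gap as large as 1505 in 1 of 100 draws, the real one, with 1452 next, when 3 of the 4 angiotensin II arrays and 1 of the 3 shams of each substrain were exchanged. The gap was counted in either direction, whereas C57Bl/6N minus C57Bl/6J had been planned. With most angiotensin II arrays exchanged, the draw of 1452 comes near to a swap of the substrain names. The spread added by C57Bl/6J angiotensin II 1 is argued against as the whole cause. Without that array the C57Bl/6J count was 116 and the C57Bl/6N count 2265, and the C57Bl/6N count was at least 950 with any array left out. The 4 groups share 1 estimate of spread in the fit, so these counts do not isolate the spread within C57Bl/6J. With array weights, lowest on C57Bl/6J angiotensin II 1 (0.17), the counts were 559 and 2665, so the ratio of counts was smaller. The scaling is argued against by a ratio of counts from 12.7 to 22.3 over the scalings. A larger response of C57Bl/6N hearts may underlie the gap, but a difference in the delivered dose or in the tissue taken stays open. Whether either makes the gap was not tested. Atrial markers, which bear on the tissue taken, had a negative difference in response, C57Bl/6N minus C57Bl/6J (camera adjusted p = 0.0253, a call lost with an estimated correlation). The medians of that list on the C57Bl/6N sham arrays, given above, lay far apart from one another. The test of the difference itself called 1 gene, 569 with array weights and 415 without C57Bl/6N angiotensin II 4.

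C57Bl/6N angiotensin II 4 lay below the other 3 of its group in macrophage and cell cycle genes, at 0.28 and 0.34 of their mean rise. A swapped substrain label is argued against by Entpd4, at 11.36 on this array against 12.09 to 12.41 in C57Bl/6J and 11.1 to 11.75 on the other C57Bl/6N arrays. A weaker response of that heart as a whole cannot be told apart from a difference in these groups alone: its cardiac stress rise was 0.806 of the others' mean, at 0.917 against 0.945 to 1.494, and its matrix and actin rises were 0.798 and 0.551. Those rises were measured from the C57Bl/6N shams. Measured from the mean of all 6 shams, its cardiac stress median, given above, lay inside the range of the other 3. No biological explanation was tested.

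C57Bl/6J angiotensin II 1 lay over 1 log2 unit from the other 3 of its group in 302 genes, 170 lower and 132 higher. A weaker signal is argued against by 47.7% of rows detected, inside the 46.4% to 49.3% of the other arrays, and a swapped treatment label by a cardiac stress median of 0.80 against -0.09 to 0.19 on the shams. Among the markers of the 5 main cell types, the largest median deviation was -0.21, of fibroblast markers. Atrial markers were not among the lists compared. The 302 genes were picked for deviations over 1 (median size 1.22), so whole marker lists cannot be judged against that size. A different mix of cell types, a source outside these lists, or 1 in the animal itself stays open, and no biological explanation was tested.

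Other groupings of the same arrays bear on each count. For C57Bl/6J, 1 of 35 splits, the real one, gave 129 genes or more, and the highest other gave 3. Since 1 of 35 is the lowest share these splits can give, chance is unlikely at that share but not excluded. For C57Bl/6N it was 1 of 35 with 1634 genes, but the split that set angiotensin II 4 with the 3 shams against angiotensin II 1 to 3 gave 1603, which points to a structure among these arrays. For the difference in response, 3 of 100 groupings, the real one among them, gave at least the 1 gene found, and the highest other gave 5. For the substrains under angiotensin II, 1 of 35 gave 869 or more, and the highest other 288. The split with 288 set C57Bl/6J angiotensin II 1 with C57Bl/6N angiotensin II 1 to 3, against all the other treated arrays. It therefore comes near to a swap of the substrain names. For treatment averaged over substrains the share was 1 of 100, with 1487 against 590, and for substrain averaged over treatments 1 of 100, with 187 against 8. In sham, 1 of the 10 splits gave as many as 2 genes and the highest other 0 (limma; 717 genes at an unadjusted p under 0.05 in the real split), and 10 splits are too few for a share under 0.05.

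Single arrays lay far from the other 3 of their group in 29 of 396 values tested, where chance alone gives about 1 in 20. On C57Bl/6J angiotensin II 1, log2 levels against the mean of the others were 6.76 against 8.12 for Erdr1, 5.88 against 6.63 for Rab4a, 10.4 against 9.94 for Uck2, 6.07 against 5.54 for Saa3 and 7.9 against 8.2 for Tubb2b. They were 9.24 against 8.46 for Slc2a1, 7.05 against 6.07 for Mt2, 12.18 against 12.06 for Rps19, 11.94 against 12.72 for Col4a1, 10.77 against 11.65 for Gpx3, 9.45 against 8.87 for Agtrap and 10.81 against 10.07 for Pi16. The medians there were 0.18 against -0.01 for endoplasmic reticulum stress genes and 0.03 against 0 for cardiomyocyte markers. Acta2 (12.81 against 12.33) and Lum (11.17 against 10.83) stood apart on C57Bl/6J angiotensin II 3, and Col3a1 (7.35 against 7.92) and Elovl6 (5.28 against 5.71) on angiotensin II 4. On C57Bl/6N angiotensin II 3 these were Egr2 (7.25 against 6.23), Scn4b (6.33 against 7.18), Hsd17b7 (9.81 against 9.93), Atf3 (7.23 against 6.19), Col4a1 (13.27 against 13.03) and Kcnd2 (6.09 against 6.68), and the medians of cardiac stress (1.62 against 1.03) and immediate early genes (0.5 against 0.1). On C57Bl/6N angiotensin II 4 these were Frat2 (6.22 against 5.7), Birc5 (6.51 against 7.8) and the median of endothelial markers (-0.03 against -0.26). Elovl6 on C57Bl/6J angiotensin II 4 lay under the lowest detected level there (5.529). The 5.54 of Saa3 was near the lowest detected levels of C57Bl/6J angiotensin II 2 to 4 (5.524 to 5.556).

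The responses of the substrains differed, by the test of the difference itself, in Ankrd2 and in 12 lists by camera. The fitted 2.3 on the log2 scale for Ankrd2 measures no size, since it was above background on 0 of the 10 arrays outside C57Bl/6N angiotensin II. The response was higher in C57Bl/6N for macrophage markers (adjusted p = 6.84e-12), cell cycle (5.02e-11), extracellular matrix (2.21e-07), actin cytoskeleton (9.33e-07) and ribosomal proteins (3.61e-05). Camera called cardiac stress up as well (0.0459), with a median difference of -0.03 and a mean of 0.35, and that call was lost without each of 7 arrays. The difference, C57Bl/6N minus C57Bl/6J, was negative for fatty acid oxidation (8.52e-06), ion channels (0.000958) and atrial markers (0.0253). It was negative too for oxidative phosphorylation (0.0301), cardiomyocyte markers (0.0301) and endoplasmic reticulum stress (0.0402). Fatty acid oxidation, ion channel and oxidative phosphorylation genes fell in C57Bl/6N, so for them a negative difference is a larger fall there, not a weaker response. The level of endoplasmic reticulum stress genes was higher, not lower, in C57Bl/6N sham ventricles. None of the 12 list calls held with an estimated correlation.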

How the results depend on the processing

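Background inferred from all rows, the filter on signal and the removal of 2 arrays together were chosen after the results had been seen. The main background estimate, from rows on the grid alone, was itself chosen after the files had been seen. No list or named gene that passed turned its tested direction in the alternatives run for it; those that did not pass were not compared in direction. No paired analysis was possible because replicate numbers follow the sample order and pair nothing. A chip block was not run, since no chip is given, nor other probes of a gene, with 1 row per gene. Signal over background limits dim genes: where no array of a group was above background, a fold is a bound or is left out.

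Counts of genes that moved by over 1.5 times are given here, and the cause was not tested except where fewer arrays or another threshold is the change itself. With array weights the counts were 559 (C57Bl/6J response), 2665 (C57Bl/6N response), 569 (difference in response), 30 (substrains in sham), 2240 (substrains under angiotensin II), 2619 (treatment averaged) and 1145 (substrain averaged). With background from all rows these were 67 for C57Bl/6J, 0 for the difference, 4 in sham and 113 for substrain averaged. The difference in response also had 0 genes without background correction, with normexp and offset 50, in the deposited value table and without C57Bl/6J angiotensin II 1 and C57Bl/6N sham 1 (limma throughout; 1644 genes at an unadjusted p under 0.05 as reported), and 4 with detection required on all arrays of a group. That removal of 2 arrays gave 4 genes in sham. Without a filter C57Bl/6J had 75. With only the groups compared in the fit there were 70 for C57Bl/6J, 1 in sham and 249 under angiotensin II. With at least 1.5-fold required there were 748 for C57Bl/6N, 406 under angiotensin II, 327 for treatment averaged and 61 for substrain averaged. At an adjusted p of 0.10 there were 267 for C57Bl/6J, 14 for the difference, 1443 under angiotensin II and 356 for substrain averaged. With each array left out, counts ran from 1 to 178 for C57Bl/6J, 950 to 2265 for C57Bl/6N, 1 to 415 for the difference, 1 to 4 in sham, 198 to 1473 under angiotensin II, 970 to 1885 for treatment averaged and 68 to 608 for substrain averaged. With median scaling the higher share of C57Bl/6J calls was 47.8% in place of 72.9%, and with background from all rows 56.7%. Of 79 list calls, 73 were lost with an estimated correlation and 36 with fry; over all fits with 1 array left out, list calls were kept 1039 times and lost 67 times, and calls of named genes kept 2674 and lost 546 times.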

Other observations

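Averaged over both treatments, genes of endoplasmic reticulum stress lay higher in C57Bl/6N than in C57Bl/6J, with 5 of 16 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 4.37e-06; adjusted p = 0.273 with an estimated correlation). The list was called in sham (median 0.40) and not under angiotensin II (median 0.20, camera adjusted p = 0.115). Genes of the circadian clock lay lower, with 0 of 12 past the threshold over all genes in limma and 5 adjusted over the list alone (camera adjusted p = 0.00641; adjusted p = 0.273 with an estimated correlation). Their median was -0.39 and -0.37 on C57Bl/6N angiotensin II 1 and 3 and -0.29 on C57Bl/6N sham 3, against -0.03 to 0.06 on the other 4 C57Bl/6N arrays. In C57Bl/6J it was 0.39 on angiotensin II 1 and -0.04 to 0.20 on the other 6. The hours at which tissue was taken are not given in the sources used here.

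Averaged over both substrains, angiotensin II lowered 2 of 15 endothelial cell markers, the same number adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.473 with an estimated correlation), and raised 2 of 7 erythroid markers, again the same number (camera adjusted p = 0.0417; adjusted p = 0.473 with an estimated correlation). The endothelial call ended without C57Bl/6J sham 1 (adjusted p = 0.0804), C57Bl/6J angiotensin II 3 (0.0542), C57Bl/6N sham 1 (0.0523), C57Bl/6N angiotensin II 1 (0.0528) or C57Bl/6N angiotensin II 2 (0.0597). The erythroid call ended when any of 7 arrays was left out, with adjusted p from 0.055 to 0.152.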
